A study of Mus musculus with 12 samples.

How the data were processed

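Cochleae of C57BL6j mice were taken at 4, 15 and 45 weeks of age, without the vestibular organs, and pooled in groups of 5 per the series' design text. Per the labels' protocols, total RNA was extracted with a column kit and biotin-labelled cRNA was hybridised to Illumina mouse BeadChips. The labels name 2 biological replicates (a and b) per age and 2 technical replicates of each, which gives 12 arrays. Whether the 5 in a pool were cochleae or mice is not given in the sources used here.

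The deposited value table holds log2 values for 45281 probes, which the authors had normalized between arrays before deposit. This follows from the values: the sorted columns of the 12 arrays are identical (largest difference 0), as quantile normalization leaves them. The background correction, the software and its version are not given in the sources used here. Quantile normalization forces 1 distribution on every array, so that a shift of most transcripts in 1 direction cannot be seen. A second deposited table has 12 value columns and 12 detection columns whose names match no sample label, and none of these columns was used. Statements on detection above background were therefore not made, and the planned start from that table with a fresh normalization was replaced by the authors' normalized values.

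Probes were named from the platform annotation. It gives 1 gene symbol for 34885 probes, several for 18 and none for 10378, and probes of the last kinds were not named. Of the named probes 34807 were matched by gene number to RefSeq names of the assembly GRCm38.p6. No coordinates are printed, since the build of the array design is not given in the sources used here. Different probes of 1 gene were tested separately.

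The 2 arrays of a pool were averaged, which left 2 pools per age as replicates. Probes with a mean level above the median of all probes (5.87) were tested, which left 22640 probes, 3425 of them without a single gene name. One linear model over the 3 ages was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), with 3 residual and 3.84 prior degrees of freedom, and gave the 3 comparisons as older minus younger. P-values were adjusted by the Benjamini-Hochberg method within a comparison, and an adjusted p under 0.05 was called. SE is the moderated standard error of the log2 difference.

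A set of 37 gene lists of cochlear, bone, blood, immune, muscle, nerve and epithelial cell types and of cell processes was fixed before the data were examined. It named 876 genes, 13 of them in more than 1 list, and 805 were found in the annotation. Lists were tested with camera at a preset correlation of 0.01 between genes, on the brightest probe of each of 12595 genes, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. Genes were named by a rule set at the same time: since every comparison called fewer than 5 probes, the 5 higher and the 5 lower of smallest p, up to 4 members of each called list with the largest change in its direction, and fixed cochlear and sex-linked genes. Genes outside the rule are said to have been chosen after their values were seen. This also holds for the 4 hormone genes where the rule does not name them.

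The test was checked on 20 simulated data sets of 22640 probes with variances drawn from limma's fitted prior and 200 probes changed at 45 weeks. For the comparison of 15 with 45 weeks, 57.2% of changes of 1 log2 unit and 96.0% of changes of 2 log2 units were recovered, with 5.05% false among the calls. For 4 with 45 weeks the shares were 58.3% and 95.5%, with 5.38% false. The shares recovered depend on the 200 changes planted and on probes drawn independently. In the data Gh, at 5.26 from 15 to 45 weeks, was not called. An absence of calls therefore does not show that changes of 2 log2 units are absent. In the same simulations over 12595 genes, a shift of 0.22 in the oxidative phosphorylation list from 15 to 45 weeks was called in 100% of data sets by camera with the preset correlation, in 0% with an estimated correlation and in 50% by fry. The size of that shift was chosen after the list's median was seen. The simulated genes were drawn independently of each other, whereas the correlation estimated within this list was 0.226. These shares therefore do not check the preset correlation on genes that vary together.

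Alternatives set at the same time as the lists were no filter, a filter at the 75th percentile of level, all 12 arrays with the pool as a random block (estimated correlation 0.296), each technical array alone, 12 arrays as if independent, the replicate letter as a block, each pool left out, only the 2 ages compared, a trended robust eBayes, array weights, 1 probe per gene, and for lists the mean over probes. Normexp background correction (offset 16), cyclic loess and the Xist level as a covariate were added after the data were seen. Median centring was void, since all arrays share 1 distribution. Figures were drawn with matplotlib 3.10.9.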

Results

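Transcript levels were measured in the cochlea of C57BL6j mice, an inbred strain known for early hearing loss, at ages of 4, 15 and 45 weeks, in tissue freed of the vestibular organs. Each age was represented by 2 pools of cochlear RNA, named a and b, and each pool was hybridised to 2 arrays, which gave 12 arrays from 6 pools. The pool was the replicate (n = 2 per age), and the number of pools limits the precision of every difference below. Levels are log2 values on the authors' normalized scale, on which every array had a median of 5.89 and values ran from 5.10 to 15.00.

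Pools of the same age differed as much as pools of different ages. Over the 22640 probes tested, arrays of 1 pool correlated across probes with r between 0.983 and 0.997. Arrays from different pools of 1 age had a median r of 0.978 and arrays of different ages a median r of 0.977. The sex-linked genes separated the pools within 2 of the ages. Xist, transcribed from the inactive X chromosome of females, lay at 8.56 in pool b at 4 weeks and 7.60 in pool b at 45 weeks, and between 5.85 and 5.95 in the remaining 4 pools. The Y-linked gene Eif2s3y lay at 5.53 and 5.65 in those pools b and between 9.54 and 9.81 in the others, and the Y-linked Kdm5d at 5.57 and 5.67 against 6.72 to 6.98. Uty, a dimmer Y-linked gene, lay at 5.97 and 6.10 against 6.19 to 6.33. Both 15-week pools had the low Xist and high Eif2s3y levels of pool a at the other ages.

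The comparison of 4 with 15 weeks asked which transcripts differ between the youngest cochleae and those of adult mice. Relative to the other genes measured, lists of bone, blood and connective tissue genes rose and lists of immune response, skeletal muscle, airway epithelium and clock genes fell, by a test that assumes a small fixed correlation between genes. None of these lists passed with that correlation estimated from the data (adjusted p = 0.666 to 0.743 with an estimated correlation). That version also called 0% of simulated shifts of the oxidative phosphorylation list. Its failure, here and in the comparisons below, therefore cannot decide for or against a list. The osteoblast and osteocyte list rose by a median of 0.29 on the log2 scale, with 15 of its 16 genes higher at 15 weeks. The B cell and plasma cell list rose by a median of 0.18, with 18 of 19 genes higher, and the erythroid list by 0.20, with 15 of 20 higher. The skeletal muscle list had a median of -0.49, with 23 of 24 genes lower at 15 weeks.

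Among the bone genes, Ifitm5 differed by 0.65 (SE 0.61), Col1a1, which encodes a chain of type I collagen, by 0.64 (SE 0.48), Mepe by 0.45 and Bglap, which encodes osteocalcin, by 0.44. For Col1a1 the arrays of 1 pool differed by more, at 10.08 and 8.48 in pool b at 4 weeks and 10.5 and 9.09 in pool a at 15 weeks. The fibrillar collagen and matrix list rose by a median of 0.08, with 18 of 26 genes higher, among them Eln, the elastin gene, at 0.61, Col5a2 at 0.51 and Sparc at 0.50. Of the B-lineage genes, Fcrla differed by 0.81, Vpreb1 by 0.65, Igll1 by 0.62 and Cd79b by 0.61. Vpreb1 and Igll1 encode the surrogate light chain of B cell precursors. Of the erythroid genes, Rhag differed by 0.52, Car2 by 0.50, Hemgn by 0.42 and the red cell transcription factor gene Klf1 by 0.33. At 15 weeks, arrays of 1 pool differed by more for Rhag (7.56 and 6.46 in pool a) and Car2 (8.76 and 9.82 in pool b). The Schwann cell and myelin list rose by a median of 0.10, with 14 of 18 genes higher, led by Fa2h at 0.39, Ugt8a at 0.31, S100b at 0.30 and Pmp22 at 0.25. The list of spiral ligament and limbus fibrocytes rose by a median of 0.08, with 11 of 18 genes higher, led by Slc4a11 at 0.60, Otor at 0.41, Otos at 0.39 and Cemip at 0.20. The endothelial list rose by a median of 0.10, with 14 of 18 genes higher, including Cldn5 at 0.49, Tek and Flt1 at 0.29 and Sox18 at 0.29. The pericyte and smooth muscle list rose by a median of 0.11, with 11 of 13 genes higher, including Rgs5 at 0.53, Myh11 at 0.28, Tagln at 0.24 and Acta2 at 0.22. For other genes named here too, though not all, arrays of 1 pool differed by more than the ages. At 15 weeks Eln read 7.115 and 8.21 and Cldn5 9.06 and 9.99 in pool b, and Rgs5 7.36 and 8.39 in pool a. Fa2h read 9.01 and 8.20 in pool b at 4 weeks. By camera with an estimated correlation the myelin, fibrocyte, endothelial and pericyte lists did not pass either (adjusted p = 0.666 for each).

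On the falling side, the skeletal muscle list was led by Myh4, a fast myosin heavy chain gene, at -1.49 (SE 0.60), Sln at -1.45 (SE 0.81), Ckm at -0.78 and Mybpc2 at -0.76. The antigen presentation list had a median of -0.21, with 18 of 20 genes lower, led by the class II genes H2-Eb1 at -0.71 and H2-Ab1 at -0.54, the peptide transporter gene Tap1 at -0.46 and H2-Aa at -0.36. The interferon response list had a median of -0.13, with 24 of 28 genes lower, including Ifit3 at -0.69, Gbp2 at -0.45, Ifi27l2a at -0.38 and Oasl2 at -0.32. The complement and inflammation list had a median of -0.16, with 17 of 21 lower, including Cfb at -0.68, Ccl7 at -0.60, Ccl8 at -0.51 and C4b at -0.38. The respiratory and ciliated epithelium list had a median of -0.24, with 12 of 14 lower, including Reg3g at -1.33, Krt14 at -0.84, Dnali1 at -0.39 and Krt18 at -0.34. Its level differed as much between the pools of an age, at 8.72 in pool b and 7.96 in pool a at 4 weeks, 8.44 in pool a and 7.77 in pool b at 15 weeks, and 8.36 in pool a and 8.04 in pool b at 45 weeks. The circadian clock list had a median of -0.26, with 13 of 15 lower, including the clock output gene Dbp at -0.75, Per2 at -0.70, Ciart at -0.60 and Per1 at -0.58. Both arrays of pool a at 15 weeks lay below every 4-week array for these genes. The arrays of pool b at 15 weeks read 8.69 and 7.75 for Per2, 7.52 and 6.60 for Ciart and 8.855 and 7.89 for Per1. The first of each lay within the 4-week readings (8.47 to 8.89, 7.18 to 7.745 and 8.33 to 9.01). For Per2, Ciart and Per1 the gap within this RNA thus exceeded the difference between ages.

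These 14 of 37 lists passed camera, a test of whether a list's genes shift relative to the other genes, with adjusted p between 9.11e-06 for the B cell and plasma cell list and 0.0269 for the fibrocyte list. With an estimated correlation 0 of the 14 passed, and 0 lists had an unadjusted p under 0.05. This loss cannot be laid to correlated genes alone. The estimated version called 0% of simulated shifts, and the pericyte list was lost at an estimated correlation of -0.020, below the preset 0.01. Fry, which tests whether a list's genes move 1 way on balance, called 0 lists in either direction (smallest adjusted p = 0.899, with 1 list at an unadjusted p under 0.05). Each call ended without at least 1 pool. Without pool b at 4 weeks 11 of the calls ended (adjusted p = 0.0827 to 0.751), without pool a at 4 weeks 2 (0.178 and 0.294), without pool a at 15 weeks 4 (0.0775 to 0.300), and without pool b at 15 weeks 8 (0.0394 to 0.579). The osteoblast and osteocyte list then fell without pool b at 15 weeks, with a median of -0.21 and an adjusted p of 0.0394, where the collagen list also had a median of -0.107 (adjusted p = 0.332) and the complement list 0.0252 (0.383). The antigen presentation list then pointed up by its test, with a median of -0.0328 (adjusted p = 0.579), and the skeletal muscle list had a median of 0.13 without pool a at 15 weeks (adjusted p = 0.300). Without pool b at 4 weeks 5 lists in all were called. The medians then shrank to 0.0405 for the erythroid, 0.097 for the osteoblast and 0.0475 for the fibrocyte list, and to -0.0489 for the airway, -0.0343 for the interferon, -0.0669 for the complement and -0.207 for the muscle list, while the myelin list had 0.20. Without pool a at 4 weeks the myelin list had 0.0206 and the pericyte list 0.0262, whereas the osteoblast (0.56), collagen (0.15), B cell (0.35), endothelial (0.15), interferon (-0.25), complement (-0.25), muscle (-0.79) and airway (-0.50) lists moved further from 0. Without pool a at 15 weeks the medians were 0.20 for the myelin, 0.83 for the osteoblast, 0.35 for the collagen, 0.27 for the B cell, -0.41 for the antigen presentation, -0.27 for the complement and -0.43 for the airway list. Without pool b at 15 weeks they were 0.11 for the erythroid, 0.20 for the pericyte, -1.18 for the muscle and -0.077 for the airway list. With the Xist level of each pool as a covariate, a fit chosen after the data were seen, 6 lists were called, 5 of the 14 among them (myelin, collagen, endothelial, pericyte and clock). The other calls ended, with medians of -0.0476 for the muscle (adjusted p = 0.702), 0.0282 for the erythroid (0.328), -0.078 for the airway (0.507), 0.12 for the osteoblast (0.169), 0.10 for the B cell (0.241), -0.11 for the antigen presentation (0.169), -0.0803 for the interferon (0.513), -0.0677 for the complement (0.558) and 0.12 for the fibrocyte list (0.126). Over all alternatives the adjusted p of the 14 lists ran from 3.62e-27 to 0.951.

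No single probe passed limma's test at an adjusted p under 0.05 between 4 and 15 weeks (smallest adjusted p = 1.00), 302 probes had an unadjusted p under 0.05, 151 of them higher and 151 lower at 15 weeks, and 1132 would be expected by chance. The 5 higher probes of smallest p had no gene name, with log2 differences between 1.29 and 2.14, ILMN_2538531 being 1 of them (7.84 ± 0.40 at 4 weeks and 9.89 ± 0.08 at 15 weeks, SD, n = 2). The SD of the pools leaves out a wide gap between arrays of the same RNA: the 2 arrays of pool b at 15 weeks read 11.62 and 8.28 for this probe, and 10.72 and 7.34 for ILMN_1233982, another of the 5. The 5 lower genes were Sftpd, which encodes surfactant protein D, at -1.78 (SE 0.26), the keratin genes Krt17 at -1.04 (SE 0.16) and Krt14, Cyp2a5 at -0.79 and the matrix metalloprotease gene Mmp3 at -1.32. Among higher probes with a gene name, chosen after their values were seen, the smallest p belonged to Prg3 at 0.61, Isg20 at 0.56, the clock gene Arntl at 0.73, Slc31a2 at 0.46 and Rhag. Within its list of 14 airway genes, Krt14 alone passed adjusted over the list alone (adjusted p = 0.00731), as did Prg3 in the mast cell, basophil and eosinophil list (0.0138) and Mmp3 in the senescence list (0.0278), while 0 passed over all probes tested. With all 12 arrays and the pool as a random block, 2 probes were called, Krt17 and Sftpd, both lower at 15 weeks.

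The comparison of 15 with 45 weeks covered the interval from adult to middle-aged mice. Transcripts of 4 pituitary hormone genes, Gh, Prl, Cga and Tshb, lay higher in both 45-week pools than in any younger pool, though none passed the test over all probes. Gh, which encodes growth hormone, lay at 6.53 ± 0.92 (SD, n = 2) at 15 weeks and 11.78 ± 0.12 at 45 weeks, a log2 difference of 5.26 (SE 0.46). Prl, which encodes prolactin, lay at 5.87 ± 0.40 and at 10.47 in pool a and 14.00 in pool b at 45 weeks, a difference of 6.36 (SE 0.98). Genes of oxidative phosphorylation rose by a median of 0.22, with 48 of 53 genes higher (camera adjusted p = 8.80e-09, and adjusted p = 0.892 with an estimated correlation).

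Cga, the gene of the subunit shared by the glycoprotein hormones, differed by 1.57 (SE 0.14) and Tshb, which encodes the beta subunit of thyrotropin, by 1.24 (SE 0.12), both higher in each 45-week pool than in each 15-week pool, as genes of smallest p tend to be (39.7% of all probes had pools that did not overlap, against 33.3% by chance). Other hormone genes of the pituitary differed less: Pomc lay at 6.64 and 5.88 in the 45-week pools and at up to 5.92 in the younger ones, Fshb at 5.65 and 5.44 against up to 5.48, and Lhb at 5.87 and 5.86 against up to 5.75. The 2 arrays of pool b at 15 weeks read 8.21 and 6.14 for Gh. These 4 genes and Dlk1, at 1.21 (SE 0.19), had the smallest p among the higher probes. Their adjusted p was 0.136 for Gh, Cga and Tshb and 0.606 for Prl and Dlk1, so that none passed. The younger levels lie near the median of the arrays and detection calls were not used here, so a difference from them may be understated. On the lower side, the smallest p belonged to the unnamed probe ILMN_2474052 at -0.91, Celf2, an RNA-binding protein gene, at -0.76 (SE 0.14), the RNA helicase gene Ddx3x at -0.66 (SE 0.12), Nhsl2 at -0.61 and the kinase gene Hipk2 at -0.77. The SE rests on pool means and leaves out gaps between arrays of 1 RNA. For Ddx3x the arrays of pool a at 15 weeks read 10.1 and 11.11, against 9.60 to 10.11 over the 45-week arrays. Kdm6b, at -0.75, was the next named gene, chosen after its values were seen.

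**Figure D1:**
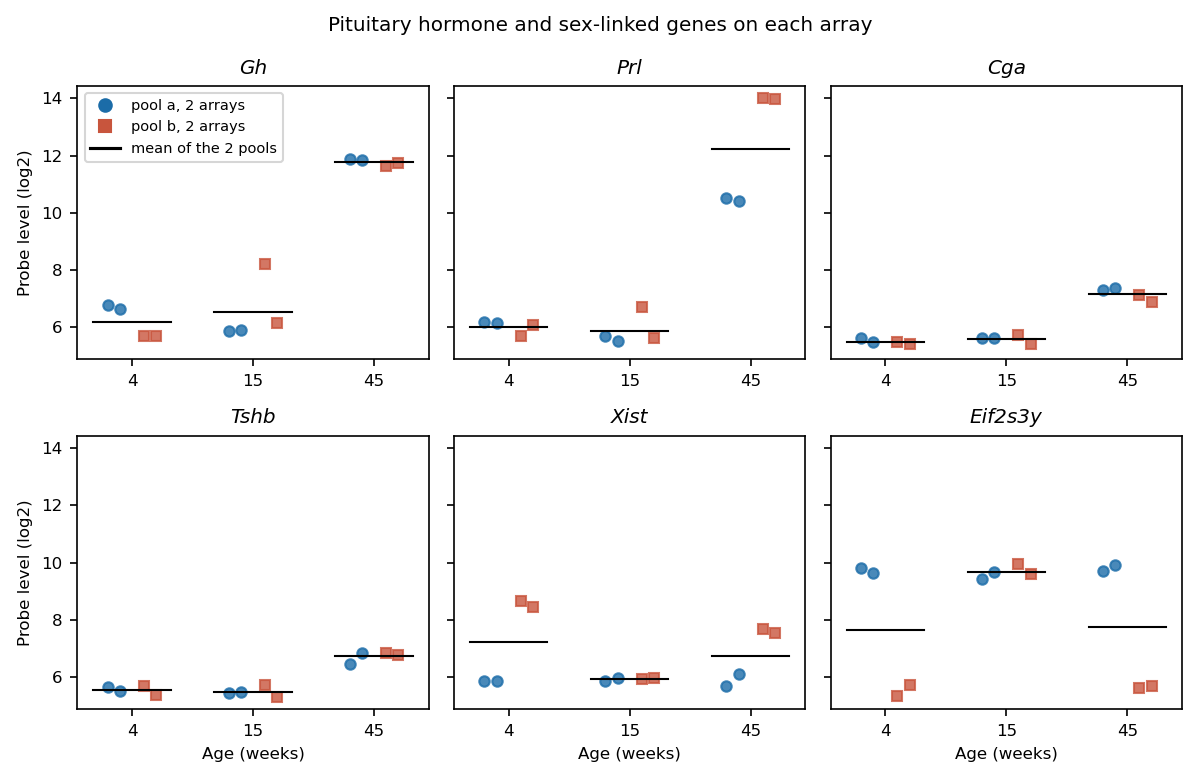
Level of 6 genes on each array (vertical axis, log2) at 4, 15 and 45 weeks (horizontal axis), with circles for pool a, squares for pool b, 2 arrays per pool and a line at the mean of the 2 pools. Gh stood at 11.87 and 11.70 in the 45-week pools and at no more than 7.18 in any younger pool, while Xist and Eif2s3y set pool b at 4 and at 45 weeks apart from the other 4 pools.

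The call of the oxidative phosphorylation list held without each pool in turn. Over its alternatives the adjusted p ran from 9.08e-10 to 0.892. Its mean level was 11.46 and 11.51 in the 15-week pools and 11.67 and 11.76 in the 45-week pools. The largest differences were those of the complex I subunit genes Ndufb7, at 0.72 (SE 0.17), and Ndufa2, at 0.54 (SE 0.18), the ATP synthase subunit gene Atp5e, at 0.69 (SE 0.31), and Cyc1, which encodes cytochrome c1, at 0.49 (SE 0.19). The skeletal muscle list rose by a median of 0.49, with 24 of 24 genes higher (adjusted p = 0.00109; adjusted p = 0.892 with an estimated correlation), led by Sln at 1.30 (SE 0.81), the myoglobin gene Mb at 1.04 (SE 0.65), Tnnc2 at 0.90 and Eno3 at 0.90. Its level differed as much between pools of 1 age, at 8.25 and 9.50 at 15 weeks and 8.92 and 9.98 at 45 weeks. Without pool a at 15 weeks its median was -0.06 (adjusted p = 0.723), and without pool b at 45 weeks, at a median of 0.0897, it was not called either (adjusted p = 0.914, with a lowest over its alternatives of 1.72e-13), nor was it with the Xist covariate (adjusted p = 0.0714). Its median was 1.18 without pool b at 15 weeks and 1.15 without pool a at 45 weeks. The osteoclast list was not called by camera (adjusted p = 0.306), though fry called it for changes in either direction (adjusted p = 0.00243), and its genes Tnfrsf11a, the receptor gene of the osteoclast differentiation factor, at -0.54 and Mmp9 at -0.47 passed adjusted over the list alone (adjusted p = 0.0282 for each). Dlk1 in the imprinted and postnatal growth list (0.00612), Prg3 at 0.58 (0.0197) and Krt14 at 0.64 (0.0329) also passed adjusted over the list alone, and 0 genes passed over all probes. None of the 53 oxidative phosphorylation genes and none of the 24 muscle genes passed in either way.

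Limma called 0 probes between 15 and 45 weeks, and 1845 probes had an unadjusted p under 0.05, 907 higher and 938 lower at 45 weeks. By fry 0 lists moved 1 way (smallest adjusted p = 0.561, with 2 lists at an unadjusted p under 0.05). With the pool as a random block over 12 arrays 6 probes were called, those of Gh, Prl, Cga, Tshb, Dlk1 and ILMN_2474052. Leaving out pool a at 45 weeks gave 1 call, Prl, and leaving out pool b at 45 weeks gave 12. The 2 called lists became 10 without pool a and 7 without pool b at 15 weeks, and 6 without pool a and 4 without pool b at 45 weeks.

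**Figure D2:**
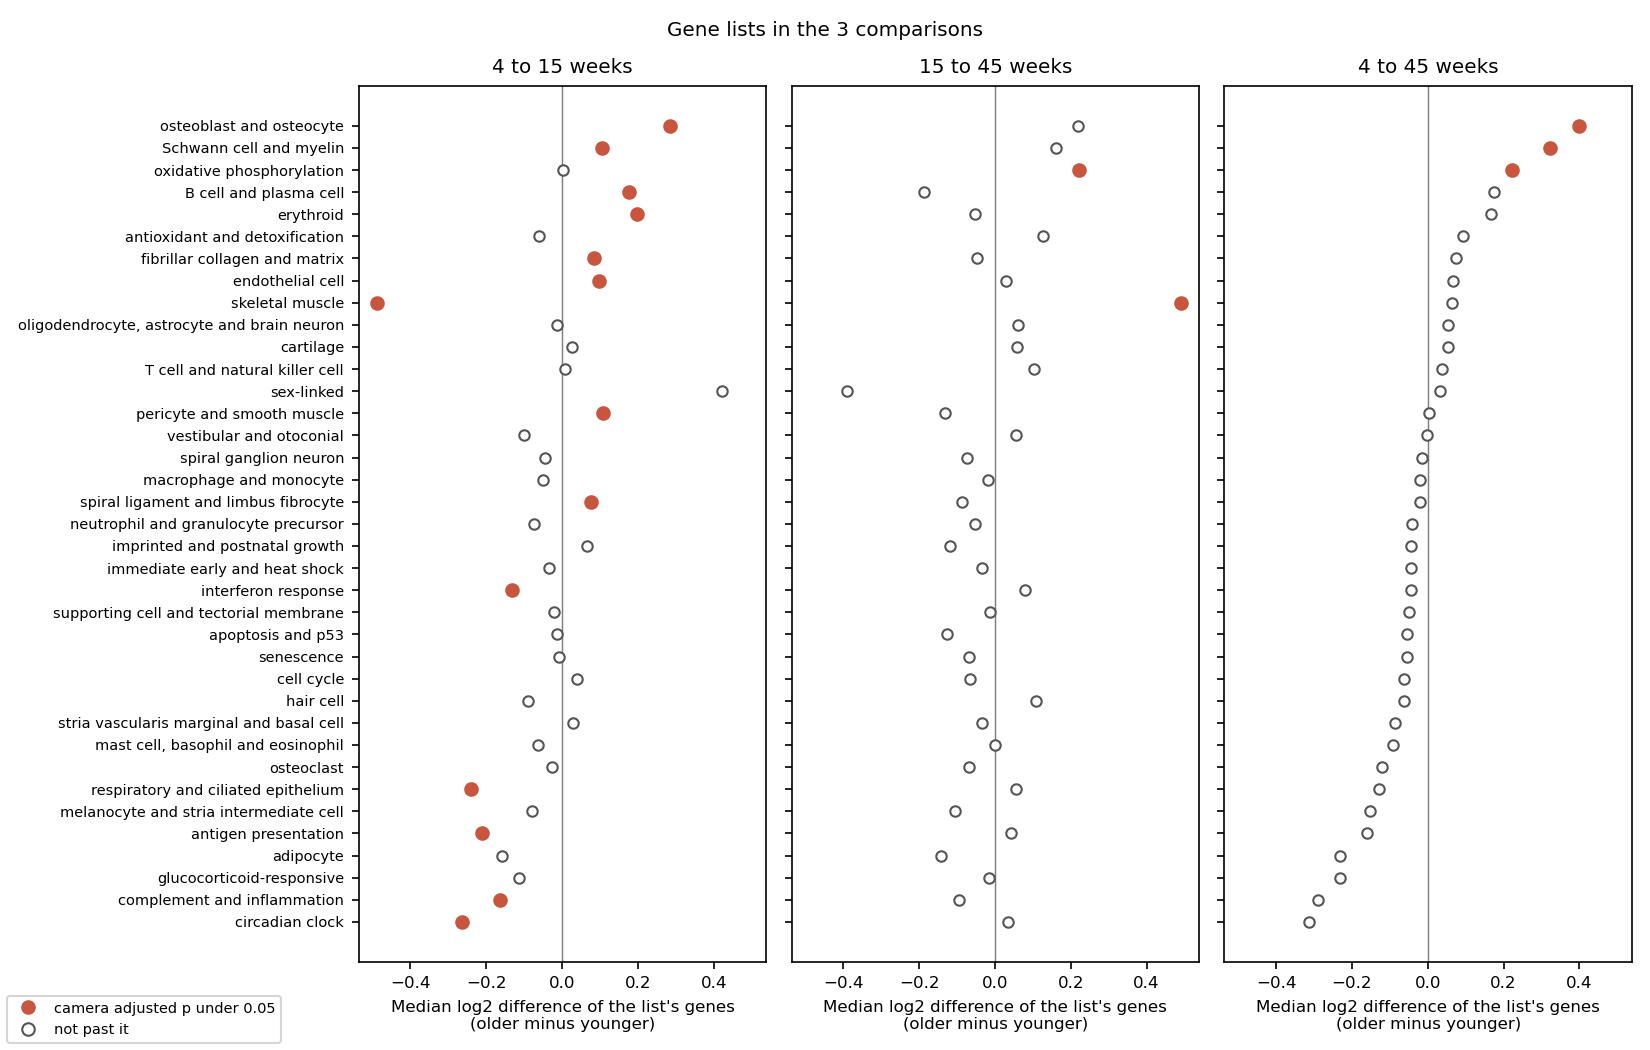
Median log2 difference of the genes of each of 37 lists (horizontal axis, older minus younger age) in the 3 comparisons, with filled points for lists that passed camera at an adjusted p under 0.05. The comparison of 4 with 15 weeks had 14 such lists, that of 15 with 45 weeks 2 and that of 4 with 45 weeks 3.

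The comparison of 4 with 45 weeks spanned the whole range of ages. Lists of bone, myelin and oxidative phosphorylation genes rose by camera with its fixed correlation, and none of the 3 passed otherwise (adjusted p = 0.995 with an estimated correlation for each). The largest differences of single probes were those of Prl and Gh. The osteoblast and osteocyte list rose by a median of 0.40, with 15 of 16 genes higher at 45 weeks, and the Schwann cell and myelin list by 0.32, with 13 of 18 higher. The oxidative phosphorylation list rose by 0.22, with 45 of 53 higher. Gh differed by 5.60 (SE 0.46), Prl by 6.22 (SE 0.98), Cga by 1.67 (SE 0.14) and Tshb by 1.18 (SE 0.12).

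In the bone list Ifitm5 lay at 8.21 and 9.70 (SE of the difference 0.61), Bglap differed by 1.10 (SE 0.52), Col1a1 by 0.97 (SE 0.48) and the alkaline phosphatase gene Alpl by 0.89 (SE 0.37). For Col1a1 the arrays of 1 pool differed by more, at 10.35 and 8.64 in pool a at 45 weeks and 10.08 and 8.48 in pool b at 4 weeks. In the myelin list Fa2h, which encodes the fatty acid hydroxylase of myelin galactolipids, differed by 0.91 (SE 0.20), the small heat shock protein gene Cryab by 0.57, Ncmap by 0.56 and S100b by 0.56, while other Schwann cell genes were lower, with Gldn at -0.38, Egr2 at -0.22 and Sox10 at -0.16. The list of oligodendrocyte, astrocyte and brain neuron genes was not called (median 0.05, with 7 of 13 genes higher, adjusted p = 0.508). Among its members, chosen after their values were seen, the myelin gene Mog differed by 0.67 and the astrocyte gene Gfap by 0.92, while the astrocyte genes Aqp4 and Aldh1l1 differed by -0.07 and -0.08 and the neuronal genes Zic1 and Cbln1 by -0.58 and -0.30. Mobp, Opalin and Olig1, at 0.58, 0.52 and 0.36, owed their difference mostly to pool a at 45 weeks (9.07, 6.74 and 9.40), since pool b lay at 7.99, 5.93 and 8.65 against 7.96, 6.03 and 8.82 in pool a at 4 weeks. In the oxidative phosphorylation list Atp5e differed by 0.78 (SE 0.31), Ndufb7 by 0.70 (SE 0.17), Atp5g2 by 0.65 (SE 0.13) and Cyc1 by 0.49. Camera gave an adjusted p of 0.0119 for the bone list, 0.0284 for the myelin list and 1.70e-06 for the oxidative phosphorylation list, each lost with the correlation estimated. The bone list was not called without pool b at 4 weeks (adjusted p = 0.482), whereas the other 2 calls held without each pool in turn. Without pool a at 4 weeks the medians were 0.68 for the bone list and 0.12 for the oxidative phosphorylation list. With the Xist covariate the bone list had an adjusted p of 0.0577 and a median of 0.41, and over its alternatives the adjusted p ran from 2.6e-05 to 0.995, against 0.0113 to 0.995 for the myelin list and 1.29e-08 to 0.995 for the oxidative phosphorylation list. The 3 called lists became 13 without pool a at 4 weeks, 6 without pool a or pool b at 15 weeks, 9 without pool a at 45 weeks and 11 without pool b at 45 weeks.

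Apart from the hormones, the higher probes of smallest p were Prg3, an eosinophil granule protein gene, at 1.19 (SE 0.12), from 9.06 at 4 weeks to 10.25 at 45 weeks, and Fam178b at 1.03 (SE 0.12). The lower ones were ILMN_2474052 at -1.35, Esm1, an endothelial proteoglycan gene, at -0.80 (SE 0.11), Ddx3x at -0.87 (SE 0.12), Ltf, which encodes lactoferrin of neutrophil granules, at -1.03 (SE 0.14), and Nhsl2 at -0.79 (SE 0.12). Mmp9, the next named gene and chosen after its values were seen, differed by -0.74. Each of these named genes had both 45-week pools beyond both 4-week pools, which selection by smallest p favours and which held for 45.0% of all probes, against 33.3% by chance. Their adjusted p lay between 0.101 for Gh and Cga and 0.271, so that none passed. Limma called 0 probes, and 3137 probes had an unadjusted p under 0.05, 1505 higher and 1632 lower, against 1132 expected by chance.

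Adjusted over the list alone, 13 genes passed between 4 and 45 weeks and 0 over all probes. They were Prg3 among mast cell, basophil and eosinophil genes (0.000241), Ltf and the myeloperoxidase gene Mpo, at -0.76, among neutrophil genes (0.00462 and 0.0155), Mmp9 and Tnfrsf11a among osteoclast genes (0.00332 and 0.0361), and Igf1r, the receptor gene of insulin-like growth factor, at -0.85, and Dlk1 among imprinted and growth genes (0.00261 for each). The others were Tap2 at -0.79 and the class I gene H2-K1 at -0.76 in antigen presentation (0.0235 and 0.0284), Laptm5 at -0.74 and Tyrobp at 0.72 among macrophage genes (0.0252 for each), Mmp3 at -1.40 in senescence (0.0206) and Bhlhe40 at -0.60 in the clock list (0.016). None of the genes of the 3 called lists passed in this way. By fry 0 lists moved 1 way (smallest adjusted p = 0.476, with 3 lists at an unadjusted p under 0.05). Fry called 5 lists for changes in either direction, the osteoclast list (0.00274), the mast cell, basophil and eosinophil list (0.00274), the senescence list (0.00654), the imprinted and postnatal growth list (0.0255) and the list of marginal and basal cells of the stria vascularis (0.0255). With the pool as a random block over 12 arrays, limma called 183 probes, 106 higher and 77 lower at 45 weeks, with Gh, Prl, Cga and Tshb among them. This fit used 1 correlation of 0.296 for all probes, which overstates the replication of probes whose pools differed more. Leaving out 15-week pool a or b gave 1 call, Gh, leaving out 45-week pool a gave 1, Prl, and leaving out 45-week pool b gave 12.

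**Figure D3:**
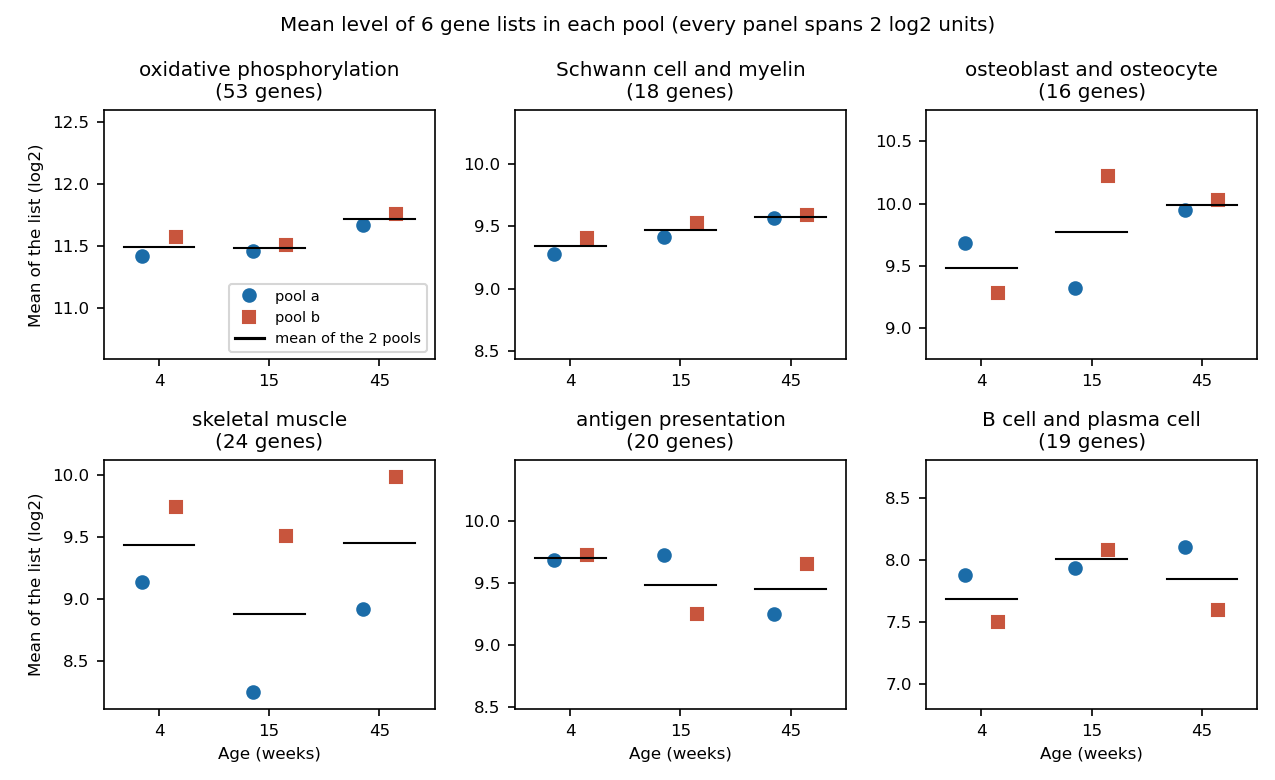
Mean log2 level of the genes of 6 lists (vertical axis) in pool a (circles) and pool b (squares) at 4, 15 and 45 weeks (horizontal axis), with a line at the mean of the 2 pools. The oxidative phosphorylation list lay at 11.67 and 11.76 at 45 weeks against 11.42 to 11.57 in the younger pools, whereas the skeletal muscle list spanned 8.25 to 9.50 within 15 weeks.

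The Schwann cell and myelin list is described above. Among the lists of hair cells, supporting cells, stria, fibrocytes and ganglion neurons, only the fibrocyte list passed camera, from 4 to 15 weeks. It did not pass with the correlation estimated (adjusted p = 0.666 with an estimated correlation). Only the list of marginal and basal cells of the stria passed fry in either direction, from 4 to 45 weeks. None of the cochlear genes fixed in advance was called. The hair cell list had 6 of 23 genes higher and a median of -0.09 from 4 to 15 weeks (camera adjusted p = 0.0632), a median of 0.11 from 15 to 45 weeks (0.248) and -0.06 from 4 to 45 weeks (0.892), where its mean of 0.01 and its test had the opposite sign. The list of spiral ganglion neurons had medians of -0.04, -0.07 and -0.02 (adjusted p = 0.501, 0.691 and 0.987), supporting cells and the tectorial membrane -0.02, -0.01 and -0.05 (0.806, 0.843 and 0.987), marginal and basal cells of the stria vascularis 0.03, -0.03 and -0.09 (0.939, 0.547 and 0.702), and melanocytes and intermediate cells -0.08, -0.11 and -0.15 (0.531, 0.389 and 0.346). The test pointed down for the stria list from 4 to 15 weeks, against its median, and up for the ganglion and supporting cell lists from 15 to 45 weeks. Otof, the otoferlin gene of inner hair cells, lay at 8.04 ± 0.12 (SD, n = 2) at 4 weeks, 7.72 ± 0.16 at 15 weeks and 7.86 ± 0.27 at 45 weeks. Myo7a lay at 6.98, 6.88 and 6.87, and Cdh23, of which this strain carries a hearing loss allele, at 5.91, 6.01 and 5.97. Coch, the cochlin gene, lay at 12.76, 12.83 and 12.75, and the connexin genes Gjb2 at 12.83, 12.95 and 12.70 and Gjb6 at 13.08, 13.17 and 13.01. Otos, the otospiralin gene of fibrocytes, lay at 12.61 ± 0.13 at 4 weeks, at 12.99 and 13.02 in the 15-week pools and at 13.16 ± 0.14 at 45 weeks, a difference of 0.55 (SE 0.13, adjusted p = 0.271) from 4 to 45 weeks. Mbp, the myelin basic protein gene, lay at 12.68, 12.82 and 13.05. Slc26a5, Pou4f3, Kcnq1 and Nefl had means between 5.47 and 5.83 at every age, below the level required for testing, and Kcnj10 and Nefh were not analysed here.

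The comparisons of 15 and of 45 weeks with 4 weeks shared the 4-week pools. No probe was called in both, as in simulations of unchanged groups against the same pools, and independent lists of these sizes would share 0. At an unadjusted p under 0.05 the comparisons had the 302 and 3137 probes given above. Their log2 differences correlated across probes with r = 0.563, against a mean of 0.501 in 100 simulations (highest 0.562). Their covariance was 0.026 against a simulated mean of 0.0254 and a highest of 0.0306, so that the 2 measures differ: the correlation lay just above all simulations and the covariance within them. Probes are not independent replicates.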

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

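No probe was called between 4 and 15 weeks except with 12 arrays and the pool as a random block (2) or 12 arrays as if independent (2). Between 15 and 45 weeks these gave 6 and 24 probes, technical array 2 alone 1 (Gh), trended robust eBayes 2 (Cga and Tshb) and normexp, chosen after seeing the data, 2 (Cga and Tshb). Between 4 and 45 weeks the counts were 183 with the random block, 1653 as if independent, which overstates the replication, 1 with technical array 2 (Gh), 1 with only the 2 ages compared (Gh), 2 with trended robust eBayes (Cga and Tshb), 2 with 1 probe per gene (Cga and Gh) and 1 with normexp (Cga). Without each pool in turn the counts ran from 0 to 0, 0 to 12 and 0 to 12 in the 3 comparisons. Calls in both comparisons with 4 weeks numbered 0 except with the random block (1) and as if independent (1). The random block used 1 correlation for all probes, which overstates the replication of probes whose pools differed more. These few called probes were named after their values were seen. The 14 lists called between 4 and 15 weeks became 9 with technical array 1, 6 with the Xist covariate, and 0 with an estimated correlation or by fry, and ran from 5 to 17 without each pool. The 2 lists called between 15 and 45 weeks became 0 with an estimated correlation or by fry and ran from 3 to 10 without each pool. The 3 lists called between 4 and 45 weeks became 5 with the random block, as if independent and with normexp, 6 with technical array 1, with only the 2 ages and with array weights, 7 with technical array 2, and 0 with an estimated correlation or by fry, and ran from 2 to 13 without each pool. The cause of these shifts was not tested, except that the estimated correlation called 0% of simulated shifts of the oxidative phosphorylation list. Without pool a at 15 weeks the skeletal muscle list turned to a median of 0.13 from 4 to 15 weeks and -0.0645 from 15 to 45 weeks, against medians of -1.18 and 1.18 without pool b at that age. Without pool b at 15 weeks, from 4 to 15 weeks, the osteoblast list turned to -0.21, the collagen list to -0.11 and the complement list to 0.0252, and the antigen presentation list turned by its test, with a median of -0.0328. Without pool a at 15 weeks these 4 medians were 0.83, 0.35, -0.271 and -0.408. A lone pool was assumed to vary like the other ages. The oxidative phosphorylation medians ran from 0.18 to 0.29 (15 to 45 weeks) and 0.12 to 0.31 (4 to 45 weeks) and were called in 19 of 21 settings each. Gh ran from 4.61 to 5.91 and Prl from 4.60 to 8.12 between 15 and 45 weeks, with 3 and 4 calls in 20 settings. Of 399 values of called lists under the alternatives 312 kept their call, 81 kept the direction only and 6 turned. A further 3014 values joined those of named genes with the counts of called lists. Of these, 80 were stronger, as a gene that passed the threshold or as a larger count, and genes were not counted apart. Signs changed in 62 values of named genes, none of which had been called. With the replicate letter as a block 0 probes were called in each comparison and 15, 3 and 3 lists. The letters share only a name: the differences of pool a minus pool b correlated at -0.112, 0.183 and -0.388 between the ages. The unnormalized table and a block for the chip were not run, since no column or chip could be tied to a sample, and median centring was void.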

Other observations

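The tests in this part were chosen after the result was seen, except that on gene span and expression level. Several secretory genes differed far more between the 2 pools of an age than between ages. Lipf, which encodes gastric lipase, lay at 11.44, 13.42 and 13.51 in pool b at 4 weeks, pool a at 15 weeks and pool a at 45 weeks, and between 5.76 and 7.08 in the other pool of each age. Bpifb1, an airway and salivary secretory protein gene, lay at 10.94, 13.22 and 12.77 in the same 3 pools against 6.17 to 6.74. Dmbt1, a mucosal glycoprotein gene, lay at 8.52, 11.01 and 10.17 against 5.71 to 5.83. The lysozyme gene Lyz1 lay at 9.45, 9.53 and 11.82 against 6.96 to 7.19, and Tff2, a trefoil peptide of mucous cells, at 9.55, 10.36 and 11.34 against 8.05 to 8.57. The median gap between the pools of an age was 0.154 over all tested probes. These genes are among the 15 with the largest mean gap and were chosen for it, as was Actb, at 8.22 and 9.74 at 15 weeks and 11.34 and 7.55 at 45 weeks for 1 of its probes.

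A second group stood out in pool a at 45 weeks alone. Pip lay at 8.92 there and at no more than 5.75 in the other 5 pools, Dcpp3 at 8.94 against at most 5.71, Bpifa2 at 9.14 against at most 6.22, Cst10 at 7.71 against at most 5.87 and Smr3a at 7.81 against at most 5.75. Pip, Bpifa2 and Smr3a are genes of salivary and other exocrine glands. They make up part of the 12 probes called without pool b at 45 weeks.

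Gh, Prl, Cga and Tshb were high in both 45-week pools, with a mean of 9.07 in pool a and 9.87 in pool b against 5.62 to 6.10 in the younger pools. Sex of the mice as the whole cause is argued against, since within each Xist class the 45-week pool exceeded the highest younger pool, by 4.25 in the Xist-high and 2.97 in the Xist-low class. Pituitary tissue carried into the 45-week pools may account for the pattern: the median of 15 other tested pituitary genes in the 45-week pools minus the rest was 0.26, above 99.99% of 10000 random lists matched on mean level, and 0.16 (99.1%) without Dlk1 and Pomc, whose values had been seen. Of 30 genes listed 15 were tested, Dlk1 at 1.25, Cd200 at 0.75 and Pcsk1n at 0.57 being higher and Scg2 at -0.66 lower, 1 of the 30 (Dlk1) stands in another list, and abundant pituitary transcripts were low, with Pomc at 6.64 and 5.88 and Lhb at 5.87 and 5.86 in the 45-week pools. Pcsk1n and Nnat (0.42) were higher in pool b alone. They lay at 7.77 and 7.31 in pool a and at 8.72 and 8.86 in pool b, against up to 7.87 and 8.10 in younger pools. Dlk1 and Cd200 were higher in both 45-week pools. Listed genes too dim to be tested went both ways. Trhr, Lhx4 and Tbx19 differed by -0.05, -0.07 and -0.12, and Pitx1, Lhb and Six6 by 0.13, 0.18 and 0.22. The percentiles thus rest in part on 1 pool. A change with age in the cochlea itself stays open and was not tested.

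The oxidative phosphorylation list was higher at 45 than at 15 weeks. Gene span and expression level as the whole cause are argued against: of 10000 random lists matched on both, 0% reached the list's median of 0.22 (highest 0.17), with a span known for 53 of 53 genes. Skeletal muscle in the sample, which is rich in these transcripts, cannot be told apart from a change in the cochlea by a fit on the level of the muscle list. At equal level of that list the difference is 0.177 of the 0.224 measured, but with 2 residual degrees of freedom its 95% interval runs from -0.104 to 0.457. This test followed 2 others, each replaced after its result was seen: the steepest slope of a single age gave 0.147 and left muscle open, and the upper limit of the common slope gave 0.165, which spoke against muscle as the whole cause but left out the error of the difference itself. Muscle as the whole cause is argued against by other values. The oxidative phosphorylation list had a median of 0.24 without pool a at 15 weeks, where the muscle list had -0.06. From 4 to 45 weeks its mean rose by 0.217 while that of the muscle list moved by 0.009. Pool a at 45 weeks had a lower muscle level (8.92) than pool b at 15 weeks (9.50) and the 4-week pools (9.14 and 9.74). Its oxidative phosphorylation level was higher, at 11.67 against 11.51, 11.42 and 11.57. The step from 11.57 is about as large as the largest difference of this list between 2 arrays of a pool (0.101), so it carries little weight. Muscle as a part of the cause and a change with age stay open, and the latter was not tested.

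A set of 29 probes without a gene name lay at least 1 log2 unit higher at 15 and at 45 than at 4 weeks, which is 0.847% of unnamed probes, against 1 probe with a name (Stfa1), 0.0052% of those. Their mean level was 7.34 and 7.75 at 4 weeks, 8.49 and 9.50 at 15 weeks and 9.47 and 8.43 at 45 weeks (pools a and b). Pool b at 45 weeks was not above the higher 4-week pool for 5 of them, and the 2 arrays of pool b at 15 weeks averaged 10.8 and 8.15. In 100 simulations of unchanged groups with each probe's own variance there were a mean of 9.82 and at most 20 unnamed probes, and a mean of 9.07 named ones. The simulated probes were drawn independently, whereas these 29 moved together between arrays. The simulated counts therefore cannot show that 29 exceeds chance. Plasma cells in the sample could bring immunoglobulin transcripts that the annotation leaves unnamed: the median of 13 tested plasma cell genes, 0.09 at 15 and 0.02 at 45 weeks against 4 weeks, lay above 98.9% and 70.8% of random lists, so that the lower percentile leaves the question open (3 of the 17 genes listed stand in the B cell list too). Mzb1 differed by 0.54 and 0.38 and Jchain by -0.07 and -0.28. Jchain lay at 5.775 to 6.36 over the pools, near the level required for testing (5.87), so its fall says little. The immunoglobulin gene Ighg1, seen among the genes of largest gap, was lowest in pool b at 15 weeks (6.06) and pool a at 45 weeks (6.18). The unnamed probes had their highest means in these pools. Ighg1 is 1 chosen gene, and the mean of pool b at 15 weeks rests on 1 array, so it cannot decide on plasma cells. The other array of that pool (8.15) lay below both arrays of pool a at 15 weeks (8.34 and 8.64). The arrays of pool b at 15 weeks were at least 1.84 apart for each of these probes. Neither plasma cells nor age can cause a gap within 1 RNA, and its source was not tested. A change with age stays open and was not tested.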
